A study of Mus musculus with 33 samples.

How the data were processed

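RNA was measured by sequencing of poly(A) libraries from 33 mouse samples in 11 groups of 3 replicates, per the labels' protocols. Mouse embryonic stem cells (mES) grew with LIF on feeder fibroblasts, and were treated on gelatin with all-trans retinoic acid at 10 µM (RA), or with the same dose of retinoic acid plus CHIR at 5 µM (RA/CHIR), in medium with 15% serum. CHIR is the usual short name of an inhibitor of the kinase GSK3 that activates Wnt/beta-catenin signalling. Per the labels' protocols, the inducers were given for 10 days, followed by 6 days in medium with 10% serum alone. Cells of each arm were collected at days 4, 7, 10 and 16. A smooth muscle cell line (SMC) and an extraembryonic endoderm stem cell line (XEN) served as references. Libraries were read as paired reads of 150 bp, about 25M per library, per the labels' protocols. The labels do not say whether the replicates are separate cultures, so the p-values may measure technical spread alone.

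The submitters' processing notes name Trimmomatic 0.33, HISAT2 2.0.4, Cufflinks and Cuffdiff, and the mouse genome build GRCm38, without parameters. The deposited file gives FPKM, that is, fragments scaled by transcript length and by library size, as the authors computed it, for 52631 genes in 33 columns. No fragment counts are part of it, so the number of reads behind each value, and the interval it would give, are unknown. Of the gene identifiers, 52398 matched a reference list of gene names, and coordinates were taken from the GENCODE M21 annotation of GRCm38. A spreadsheet had turned 13 gene symbols into dates, and these were restored from the identifiers. The 198 genes that share a symbol with another gene are not named singly. The counting is not stated to use strand, so overlapping and antisense genes, paralogs and pseudogenes may share reads. Values of exactly 0 were checked: 124 genes, of which 5 code for proteins, were at 0 in 1 library while their group had 20 FPKM or more. Such zeros are read as listed values and not as absence.

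Values were analysed as log2(FPKM + 1) without further scaling. The 16508 genes with FPKM of at least 1 in at least 3 libraries were tested with limma 3.58.1 in R 4.3.3, in a single linear model of the 11 groups over all 33 libraries, with a trended prior variance. The residual degrees of freedom were 22 and the prior degrees of freedom 3.1. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over all genes tested within each comparison. A gene was called changed at an adjusted p under 0.05 and a log2 fold change of at least 1 in size. "Rose", "fell", "higher" and "lower" in the results refer to such calls unless stated otherwise. The pseudocount of 1 compresses fold changes of weakly expressed genes. Errors of FPKM are SD over 3 libraries, and errors of log2 fold changes are standard errors of the model.

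Comparisons were RA/CHIR against RA at each day, each treated group against mES, XEN against SMC, RA/CHIR-16d against XEN, RA-16d against SMC, 16d against 10d within each arm, and the interaction, that is, the change from 10d to 16d in the RA/CHIR arm minus that in the RA arm. A set of 36 gene lists was tested in all 18 comparisons with limma's camera at a preset correlation between genes of 0.01, adjusted over all 648 pairs of list and comparison. Genes of a list were counted as higher or lower by the same rule as all genes, and again with p-values adjusted over the list alone. A further pair of reference lists held the genes higher in XEN than in SMC, or the reverse, called by the same rule with a log2 difference of at least 2. The log2 differences of RA/CHIR over RA were also correlated across genes with those of XEN over SMC.

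Genes are named by a fixed rule. In RA/CHIR against RA, the 10 highest and the 10 lowest called genes were taken, among those with a mean of at least 5 FPKM in the higher group and no overlap between the replicates, and in other comparisons the 5 highest and 5 lowest. A set of 23 identity genes was also fixed, and for each list described, the 2 to 4 called members with the largest change were to be given. The text gives fewer or none for some lists, and does not print every gene that the rule picks. For the interaction, 5 FPKM in the highest of the 4 groups was required and no rule on overlap applied. Predicted genes with Gm or Rik names and genes that share a symbol were passed over, while names of clones, such as AC131720.3, were kept. The comparisons, tests, thresholds, lists, naming rule and alternative settings were chosen before the data were examined. The alternatives were another scaling (factors of the TMM kind, or quantile normalization), a pseudocount of 0.1, other filters, a fit of only the groups compared, no variance trend, the replicate number as a block, leaving out each library in turn, adjusted p without a minimum fold change, and an estimated correlation in camera.

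The scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and the R package data.table, version 1.17.8. The steps were tested on simulated data built on RA/CHIR-16d against RA-16d with 16508 genes. Of 50 genes shifted by each size, 47 were found at a log2 change of 1.25, 49 at 1.5, 49 at 2 and 49 at 3, with 0 false calls. The shifted genes were drawn only from those above a minimum level in RA-16d, and decreases too large for a gene's level were made increases. Recovery of changes in genes below that level was therefore not tested. At an unadjusted p under 0.05, the list test called 0 of 200 simulated lists without a shift and 20 of 20 lists raised by 0.5. The simulated genes varied independently of each other, so this says nothing about lists whose members are correlated.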

Results

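The 33 libraries cover mES, 4 days of sampling in each of the RA and RA/CHIR arms, and the SMC and XEN lines, with n = 3 libraries per group. Between 11573 and 13662 genes had at least 1 FPKM in a library, and 16508 genes were tested. Across genes, the Pearson correlation of log2 values between single libraries, averaged per group or pair of groups, was 0.982 to 0.989 within groups and 0.729 to 0.977 between groups. Levels below are mean FPKM ± SD over 3 libraries, changes are log2 fold changes ± standard error, and all p-values are adjusted values from limma or its camera test. The FPKM columns sum to between 597010 and 1086371, and 1 short transcript can take a large part of a sum. AL626808.1 holds 303769.0 FPKM in mES replicate 3, and mt-Ts1 holds 89757.4 and 95422.3 FPKM in RA/CHIR-4d replicate 2 and RA/CHIR-10d replicate 1.

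The main question of the design is how adding CHIR to retinoic acid alters the course that stem cells take over 16 days. Pou5f1 (Oct4, chromosome 17, 35506018 to 35510772, GRCm38), a core factor of pluripotency, stood at 1325.8 ± 332.4 FPKM in mES. It was at 96.0 ± 2.24, 36.8 ± 1.03, 10.5 ± 1.45 and 4.31 ± 1.08 on days 4, 7, 10 and 16 of the RA arm, and at 349.5 ± 3.14, 284.6 ± 5.34, 195.0 ± 4.66 and 143.7 ± 5.15 in the RA/CHIR arm. Sox17 (chromosome 1, 4490931 to 4497354), a regulator of endoderm, stood at 72.3 ± 0.994 on day 4 and 114.5 ± 19.1 on day 16 with RA. With RA/CHIR it stood at 164.7 ± 8.22 and 361.8 ± 36.2 on these days, and in XEN at 189.1 ± 16.7. Acta2 (chromosome 19, 34241090 to 34255590), the smooth muscle actin, reached 3683.0 ± 355.2 in RA-16d, 189.2 ± 1.48 in RA/CHIR-16d and 11435.1 ± 138.2 in SMC. The Wnt target Axin2 (chromosome 11, 108920349 to 108950783) stood at 81.4 ± 1.54, 51.5 ± 1.54 and 47.9 ± 1.59 on days 4, 7 and 10 with CHIR, and at 1.57 ± 0.314 on day 16. Its levels with RA alone were 2.52 ± 0.133, 8.74, 18.3 and 6.54 ± 1.08. Cyp26a1 (chromosome 19, 37697798 to 37701536), which encodes an enzyme that degrades retinoic acid, went from 2.11 ± 0.359 in mES to 1031.2 ± 35.9 in RA-4d and 609.4 ± 14.6 in RA/CHIR-4d. The order of the arms was reversed later: on days 7, 10 and 16 every RA/CHIR library lay above every RA library. On day 10 the libraries were at 1352.8 to 1398.5 with RA/CHIR and 171.8 to 185.3 with RA.

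**Figure D1:**
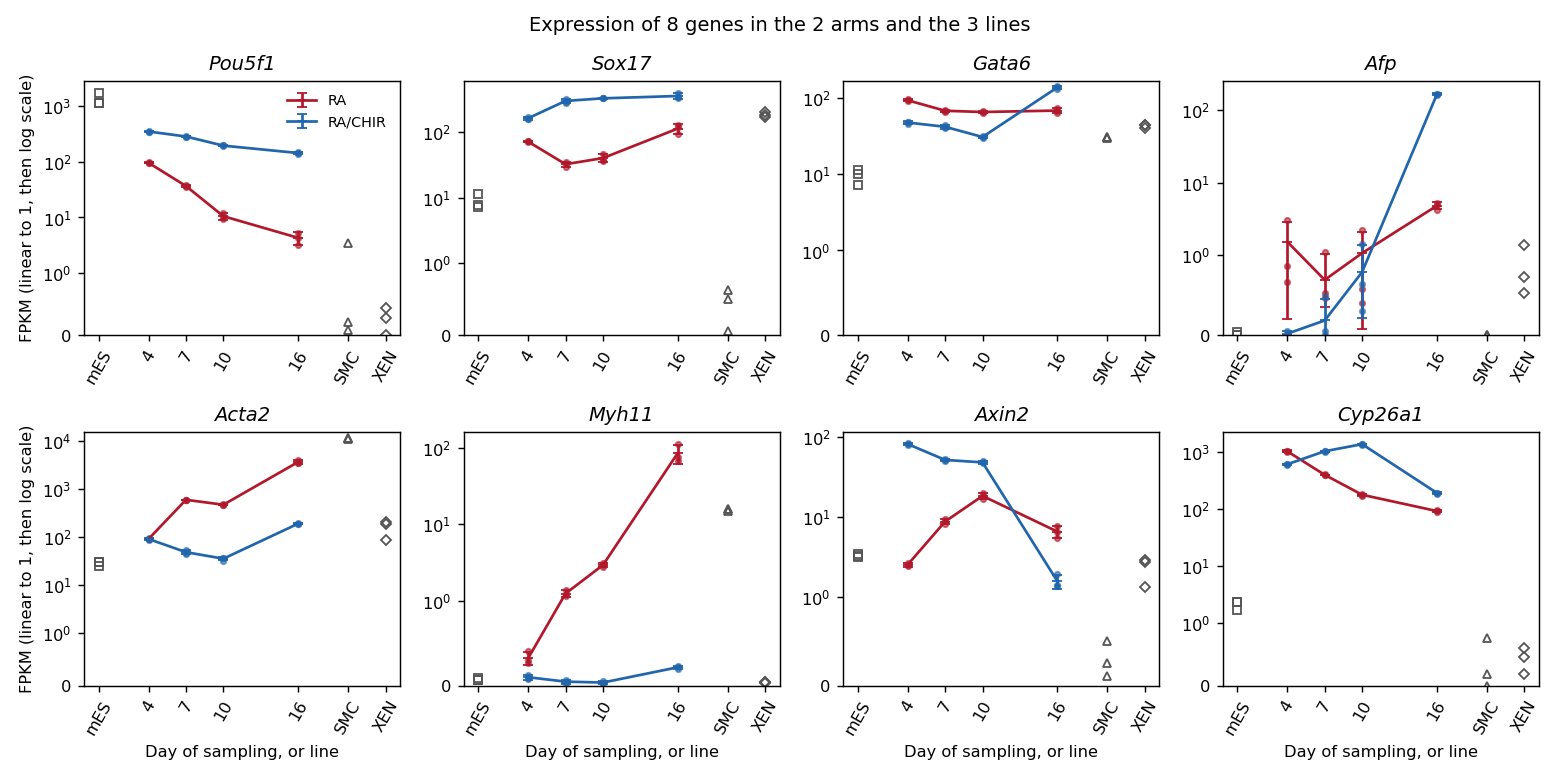
FPKM (symmetric log axis, linear up to 1) of 8 genes by day of sampling in the RA and RA/CHIR arms, with mES, SMC and XEN at the sides; points are single libraries, lines join means and bars are SD, n = 3. Pou5f1 stays at 143.7 FPKM in RA/CHIR-16d and reaches 4.31 in RA-16d, while Myh11 reaches 85.8 in RA-16d and 0.217 in RA/CHIR-16d.

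On day 4, the comparison of RA/CHIR with RA shows the early difference made by CHIR. The highest gene with CHIR was the secreted Wnt inhibitor Notum, at 93.1 ± 7.12 against 0.213 ± 0.195 FPKM (change 6.29 ± 0.15, adjusted p = 3.67e-21), and the caudal homeobox gene Cdx1 at 88.3 ± 2.94 against 0.398 ± 0.127 (6.00 ± 0.13). The ligand gene Wnt6 was at 77.0 ± 3.32 against 0.367 ± 0.155 (5.84 ± 0.23), and the transcription factor gene Sp5 at 33.5 ± 2.90 against 0.159 ± 0.139 (4.90 ± 0.14). The 10 highest also included Fgfbp3 (5.31), Tlx2 (4.65), Axin2 (4.55), Zfp36l3 (4.47), the receptor gene Fzd10 (4.23) and Cxcl14 (4.14). The extracellular matrix gene Ecm1 was lower with CHIR, at 22.0 ± 2.54 against 717.5 ± 32.1 FPKM (-4.97 ± 0.11, adjusted p = 4.12e-22). Also lower were the hormone gene Sst (-4.98), the Wnt inhibitor Sfrp5 (-4.90), the retinoid target Tgm2 (-4.77), Myl7 (-4.73), the thyroxine carrier Ttr (-4.33), the pepsinogen gene Pga5 (-4.32), Shisa3 (-4.28), Crispld2 (-4.07) and Gstm1 (-4.04). Among these 20 genes the largest adjusted p was 4.04e-15, for Myl7. Of the identity genes, Pou5f1 (1.85 ± 0.29), Nanog (1.90 ± 0.15), Sox2 (1.12), Sox17 (1.18) and Lef1 (2.95) were higher with CHIR. So was the mesoderm gene T, at a low level (1.37 ± 0.356 against 0.0172 ± 0.0297 FPKM, 1.21 ± 0.13). The endocytic adaptor Dab2 (-2.15 ± 0.13) was lower. Afp was also lower (-1.19 ± 0.28, adjusted p = 0.00103), but without RA-4d replicate 3 the change is -0.79 and it is not called. Gata4 (-0.87), Foxa2 (-0.93) and Acta2 (0.00) were not called.

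Of 22 measured Wnt/beta-catenin targets, 17 were higher and 1 lower on day 4 (median 2.03, camera adjusted p = 1.98e-14). Pluripotency genes were higher in 8 and lower in 2 of 26 cases (adjusted p = 7.36e-05), led by the nuclear receptor gene Esrrb (4.08) and by Nr0b1 (3.13), with Tdgf1 (-2.64, not separable from the pseudogene Tdgf1-ps1) on the lower side. Basement membrane and other parietal endoderm genes were lower in 13 and higher in 2 of 20 cases, among them Fst (-3.61), Plat (-3.04) and Nid1 (-1.55), with adjusted p = 7.92e-08 at the preset correlation and adjusted p = 0.1 with an estimated correlation. Primitive endoderm genes were lower in 8 and higher in 3 of 20 cases (Dab2 -2.15, Lamc1 -1.54, Cited1 2.13, Aqp8 1.98; adjusted p = 0.000103, and adjusted p = 0.309 with an estimated correlation). Retinoid response genes were lower in 7 and higher in 2 of 20 cases, with Tgm2, Cyp26b1 (-3.10) and Aldh1a2 (-2.37) lower (adjusted p = 1.31e-05). Hox genes were lower in 12 and higher in 4 of 36 cases (adjusted p = 0.00811), with Hoxb13 (-2.72) and Hoxa4 (-2.68) leading. Imprinted genes were lower in 9 and higher in 1 of 16 cases (adjusted p = 1.69e-08), with Dlk1 (-3.25), Cdkn1c (-3.03) and Mest (-3.01). Neural genes (5 lower and 2 higher of 15, Zic1 3.50, adjusted p = 0.00712) and epithelial genes (4 of 14 lower, Cldn7 -2.13, adjusted p = 0.00191) were lower as lists. Contractile smooth muscle genes had 2 lower members of 23, Pgm5 (-1.26) among them (adjusted p = 0.000703, and adjusted p = 0.22 with an estimated correlation). In total 1259 genes were called on day 4, 552 higher and 707 lower with CHIR.

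By day 7 more genes were called in each direction. The highest genes with CHIR were Notum (118.6 ± 6.62 against 4.42 ± 0.341 FPKM, 4.46 ± 0.15), the homeobox gene Pitx1 (185.4 ± 6.00 against 7.51 ± 0.592, 4.45 ± 0.10), Ffar3 (4.35), the coactivator gene Cited1 (292.9 ± 5.51 against 13.5 ± 1.58, 4.35 ± 0.16) and Cxcl14 (4.26). Next came Esrrb (25.8 ± 0.727 against 0.414 ± 0.178, 4.25), the calcium binding S100g (1291.4 ± 30.1 against 69.8 ± 2.97, 4.19), the Wnt inhibitor Wif1 (4.05), Fgfbp3 (4.04) and Smpx (4.04). Lowest were Ecm1 (36.0 ± 2.71 against 2962.3 ± 36.5, -6.32 ± 0.11, adjusted p = 3.16e-24) and Wt1 (0.298 ± 0.131 against 61.2 ± 1.97, -5.59 ± 0.08), a regulator of mesothelium and kidney. Upk3b, known from mesothelium, was listed at 0 in all 3 RA/CHIR libraries against 28.2 ± 1.13. Also among the lowest were the enteric actin Actg2 (-4.83), Nr2f1 (-4.85) and Sfrp1 (-4.62). Tgm2 (-5.44), Shisa3 (-4.67), the chemokine gene Cxcl10 (-4.58) and AC131720.3 (-5.29 ± 0.94, adjusted p = 4.05e-05, the largest of these 20 genes) were also among the lowest. Pou5f1 (2.92), Zfp42 (1.08), Sox17 (3.19 ± 0.15), Sox7 (1.59), the growth factor receptor Pdgfra (2.55 ± 0.08) and Cyp26a1 (1.38) were higher with CHIR. Dab2 (-1.14), Ttr (-3.15), Acta2 (-3.61 ± 0.16), Tagln (-2.97), Cnn1 (-2.26) and Col1a1 (-2.06) were lower, as was Myh11 (-1.10), which changes by -0.98 under quantile normalization and is then not called.

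Pluripotency genes were higher with CHIR in 15 of 26 cases and lower in 0 on day 7 (median 1.26, camera adjusted p = 5.17e-10), including Esrrb, Tcl1 (3.12) and Nr0b1 (2.76). Wnt targets were higher in 15 and lower in 2 of 22 cases (Notum, Wif1, Dkk1 3.41, adjusted p = 9.07e-09). Of the contractile smooth muscle genes, 14 of 23 were lower (median -1.26, adjusted p = 2.42e-11), with Actg2, Acta2, Tagln and Tpm2 (-2.81). Fibroblast matrix genes were lower in 9 and higher in 1 of 24 (Col3a1 -3.94, Dcn -3.42, adjusted p = 0.000137, and adjusted p = 0.122 with an estimated correlation). Primitive endoderm genes, lower as a list on day 4, were now higher in 8 and lower in 1 of 20 cases (Cited1, Sox17, Aqp8 2.73, adjusted p = 1.92e-07, and adjusted p = 0.173 with an estimated correlation). Retinoid response genes (11 of 20 lower and 3 higher, Tgm2, Aldh1a2 -3.15, adjusted p = 7.39e-06) and Hox genes (13 of 36 lower and 2 higher, Hoxa5 -2.56, adjusted p = 0.00324) were lower. So were imprinted genes (10 of 16 lower, Dlk1 -3.76, Mest -3.31, adjusted p = 3.50e-10). Cardiac genes were lower in 5 and higher in 1 of 15 (Myl7 -3.59, Nppa -3.53, adjusted p = 0.00792). Parietal endoderm genes (4 higher, 3 lower, adjusted p = 0.0825) and visceral endoderm genes (8 higher, 3 lower, adjusted p = 0.324) were not called as lists. Day 7 gave 1762 called genes, 670 higher and 1092 lower with CHIR.

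On day 10, the last day with the inducers, S100g was the most increased gene with CHIR (2552.9 ± 49.3 against 39.0 ± 7.19 FPKM, 6.01 ± 0.14, adjusted p = 6.17e-22). Ppp1r17 was at 27.7 ± 0.815 with CHIR and listed at 0 in all 3 RA libraries. Cited1 (348.2 ± 14.1 against 11.2 ± 0.985, 4.84), Cxcl14 (4.52), Pitx1 (225.7 ± 10.6 against 8.99 ± 1.77, 4.52) and Wif1 (4.37) were next. They were followed by the water channel gene Aqp8 (436.2 ± 13.6 against 20.9 ± 2.42, 4.32), the matrix protein gene Spp1 (4.26), Ffar3 (4.25) and Esrrb (4.24). Lowest with CHIR were Wt1 (0.453 ± 0.158 against 121.6 ± 5.83, -6.40 ± 0.08), Ecm1 (73.7 ± 7.32 against 6134.5 ± 91.1, -6.37), Tmem255a (-5.92), Upk3b (-5.85) and Actg2 (-5.59). The imprinted gene Nnat, Sfrp1 (-5.18) and the IGF binding protein genes Igfbp6 (-5.19), Igfbp3 (8.05 ± 0.284 against 328.9 ± 8.33, -5.19) and Igfbp5 (-5.14) followed. The largest adjusted p among these 20 genes was 6.74e-15, for Igfbp6. Pou5f1 (4.09), Gata4 (148.8 ± 6.13 against 40.9 ± 1.17, 1.84), Sox17 (3.03), Sox7 (2.58), Foxa2 (1.06), Pdgfra (3.61) and Cyp26a1 (2.95) were higher, and Gata6 (-1.07), Dab2 (-1.06), Ttr (-1.51), Acta2 (-3.71), Myh11 (-1.92) and Col1a1 (-2.62) lower.

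Primitive endoderm genes were higher with CHIR in 15 and lower in 2 of 20 on day 10 (median 1.88, camera adjusted p = 1.84e-11, and adjusted p = 0.0743 with an estimated correlation). Parietal endoderm genes were higher in 11 and lower in 1 of 20 (Lama1 3.21, Srgn 2.71, Prss12 2.39, adjusted p = 8.22e-06, and adjusted p = 0.178 with an estimated correlation). Pluripotency genes were higher in 16 of 26 (Esrrb, Fbxo15 3.39, Dppa5a 3.19, adjusted p = 3.63e-10). Of the contractile smooth muscle genes, 17 of 23 were lower (Tpm2 -3.35, adjusted p = 2.09e-11). Fibroblast matrix genes were lower in 14 and higher in 1 of 24 (Col3a1 -4.24, Col6a1 -3.48, adjusted p = 4.84e-07). Wnt targets were still higher in 12 and lower in 4 of 22 (Cdx2 2.84, Notum 2.77, adjusted p = 0.000475). Genes of the unfolded protein and integrated stress response were higher in 5 of 14 (Asns 3.49, Chac1 3.06, Trib3 2.62, adjusted p = 0.000375). Hox genes (18 of 36 lower and 2 higher, Hoxc5 -3.17, adjusted p = 5.23e-05) were lower, with imprinted genes (9 of 16 lower, Dlk1 -3.67, adjusted p = 5.16e-08) and retinoid response genes (10 of 20 lower and 2 higher, Tgm2 -4.96, adjusted p = 0.000886). A total of 2546 genes were called on day 10, 1048 higher and 1498 lower with CHIR.

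On day 16, after 6 days without inducers, apolipoprotein genes were among the highest with CHIR. The apolipoprotein gene Apoa1 stood at 178.8 ± 2.58 against 3.25 ± 0.294 FPKM (5.41 ± 0.16, adjusted p = 3.38e-20), and Apoa4 at 51.9 ± 1.47 against 0.351 ± 0.0940 (5.29). The fibrinogen gene Fgb stood at 113.0 ± 2.58 against 2.07 ± 0.259 (5.22 ± 0.07), and the alpha-fetoprotein gene Afp (chromosome 5, 90490737 to 90508907) at 168.1 ± 3.69 against 4.79 ± 0.525 (4.87 ± 0.28). Apoc2 (5.17), Apoa2 (5.06), the fatty acid binding protein genes Fabp1 (4.95) and Fabp2 (4.82), and Pramel7 (5.38) were also among the highest, and Zg16 was at 48.4 ± 3.92 with all 3 RA libraries listed at 0. Among the lowest with CHIR were the matrix genes Mgp (0.434 ± 0.437 against 273.2 ± 39.6, -7.62 ± 0.39), Mfap4 (1.83 ± 0.267 against 417.6 ± 10.0, -7.21), Eln (-6.93), Mfap2 (-6.88), Ogn (-6.42) and Lum (-6.42). Dlk1 (7.79 ± 1.91 against 1111.8 ± 72.3, -7.01), Actg2 (18.7 ± 1.21 against 1720.1 ± 209.1, -6.45), Wt1 (-6.40) and Igfbp3 (-6.33) completed the lowest 10. Apoa2 had the largest adjusted p of these 20 genes, 4.64e-12. Pou5f1 (4.79 ± 0.29), Nanog (3.27 ± 0.281 against 0.638 FPKM, 1.38), Zfp42 (2.91), Gata4 (1.77), Sox17 (1.66), Sox7 (1.66), Foxa2 (1.76), Pdgfra (1.88), Dab2 (2.03) and Ttr (4.15) were higher. Gata6 (1.0) was at the threshold, and is not called without RA-16d replicate 1 (1.0) or 2 (0.95), or RA/CHIR-16d replicate 1 (0.98) or 2 (1.0). Lower with CHIR were Acta2 (-4.27 ± 0.16), Tagln (-3.79), Cnn1 (-5.38), Myh11 (85.8 ± 24.7 in RA-16d, 0.217 ± 0.0166 in RA/CHIR-16d, -6.12 ± 0.11, adjusted p = 1.29e-24), Col1a1 (-2.52) and Axin2 (-1.55).

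As lists on day 16, visceral endoderm genes were higher with CHIR in 22 of 23 (median 2.97, camera adjusted p = 7.62e-15). Primitive endoderm genes were higher in 19 of 20 (Cubn 4.14, Aqp8 3.43, Lama1 3.31, adjusted p = 1.57e-14), and pluripotency genes in 19 of 26 with 1 lower (Fbxo15 4.42, Dppa5a 4.21, Tdgf1 3.93, adjusted p = 6.03e-12). Parietal endoderm genes were higher in 14 and lower in 1 of 20 (Srgn 4.00, Pth1r 2.97, adjusted p = 4.30e-08, and adjusted p = 0.0953 with an estimated correlation). Contractile smooth muscle genes were lower in 21 of 23 (median -2.90, Des -5.15, adjusted p = 1.98e-14) and fibroblast matrix genes in 21 of 24 (Col6a2 -5.04, adjusted p = 2.39e-12). Mesenchymal transition genes were lower in 8 and higher in 2 of 12 (Mmp2 -5.10, Cdh11 -3.44, adjusted p = 0.000458), and epithelial genes higher in 3 of 14 (Ocln 1.69, Cdh1 1.47, adjusted p = 0.0061). Wnt targets, higher on days 4 to 10, were now lower in 9 and higher in 3 of 22 (Nkd1 -3.34, Tnfrsf19 -3.18, Dkk1 2.73, adjusted p = 0.0145, and adjusted p = 0.0904 with an estimated correlation). Interferon response genes were lower in 8 of 15 (Bst2 -2.54, Isg15 -1.85, adjusted p = 0.00245). Hox genes were lower in 18 of 36 with 1 higher (Hoxc8 -2.93, adjusted p = 7.35e-06). The same held for imprinted genes in 9 of 16 (Mest -3.87, Plagl1 -3.50, H19 -3.33, adjusted p = 8.96e-07) and retinoid response genes in 8 of 20 with 2 higher (Aldh1a2 -4.43, Crabp2 -4.15, adjusted p = 0.00393). Cyp26a1 went the other way, with libraries at 185.4 to 193.8 FPKM in RA/CHIR-16d and 88.2 to 95.4 in RA-16d. Immediate early genes were lower in 7 of 11 (Fos -2.83, Nr4a1 -2.04, adjusted p = 0.00987, and adjusted p = 0.416 with an estimated correlation). Day 16 gave 3514 called genes, 1389 higher and 2125 lower. The size of the excess of lower genes depends on the scaling: 39.5% of calls were higher, but 47.7% under quantile normalization, with 1674 higher and 1836 lower. The 3 replicates of each arm did not overlap for 9114, 9354, 10295 and 10377 genes on days 4, 7, 10 and 16, which is 55.2, 56.7, 62.4 and 62.9% of the tested genes. Chance alone gives 10.0% if the libraries are independent, but the labels do not say that the replicates are separate cultures.

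**Figure D2:**
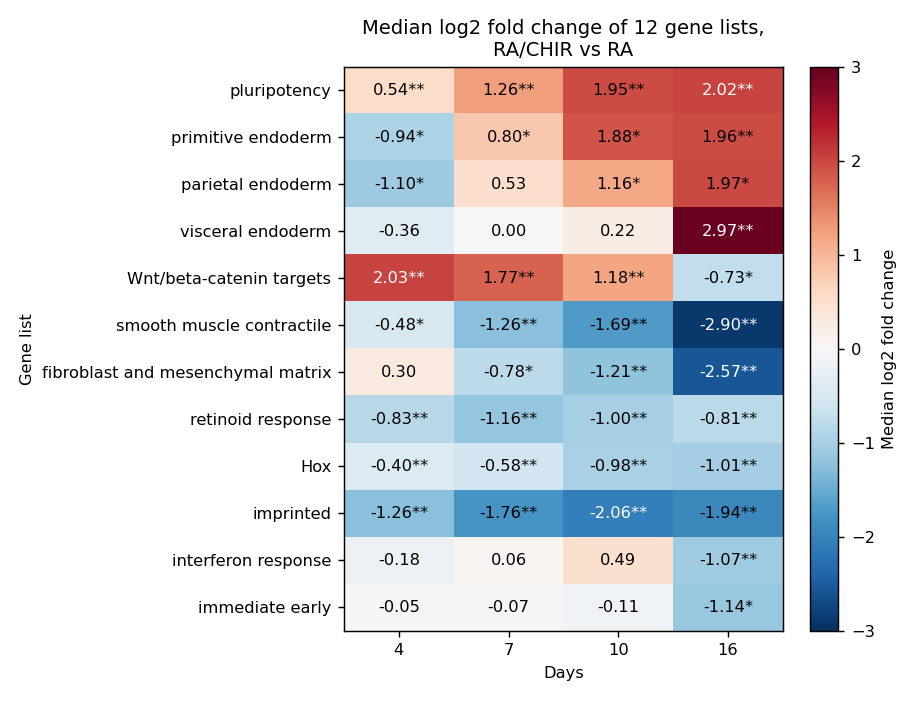
Median log2 fold change (colour, number in each cell) of 12 gene lists between RA/CHIR and RA on each day, n = 3 libraries per group; 1 asterisk marks a camera call at the preset correlation and 2 asterisks a call that also holds with an estimated correlation. Wnt targets go from a median of 2.03 on day 4 to -0.73 on day 16, and visceral endoderm genes reach 2.97 on day 16.

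Whether the CHIR effect runs along the difference between the reference lines was examined with the 713 genes higher in XEN and the 1321 higher in SMC by a log2 difference of at least 2. The XEN-high genes had median changes between RA/CHIR and RA of -0.15, 0.11, 0.40 and 0.80 on days 4, 7, 10 and 16 (camera adjusted p = 0.00286, 0.0367, 3.06e-07 and 4.34e-14), with 52, 115, 200 and 309 members higher and 110, 82, 75 and 60 lower. The SMC-high genes had medians of -0.03, -0.34, -0.52 and -1.08 (adjusted p = 0.0831, 2.69e-09, 4.35e-12 and 3.17e-23), with 105, 67, 77 and 50 higher and 156, 324, 442 and 696 lower. All 7 calls hold with an estimated correlation, the weakest being day 7 of the XEN-high genes (0.0456), which is not called under either scaling (adjusted p = 0.0595 and 0.0701) or a pseudocount of 0.1 (0.0674). A pseudocount of 0.1 also ends the day 4 call of the XEN-high genes (0.0853). Across genes, which are not independent replicates, the Pearson correlation of the RA/CHIR over RA change with the XEN over SMC difference was 0.019 ± 0.0206, 0.212 ± 0.0054, 0.286 ± 0.0089 and 0.417 ± 0.0187 (SD over single libraries) on the 4 days, and Spearman's was 0.039, 0.182, 0.242 and 0.346. These measures compare the arms with each other and do not show which arm moved. From day 4 to day 16, the mean correlation with XEN libraries went from 0.885 to 0.828 for RA and from 0.878 to 0.876 for RA/CHIR. With SMC libraries it went from 0.792 to 0.856 for RA and from 0.783 to 0.781 for RA/CHIR.

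**Figure D3:**
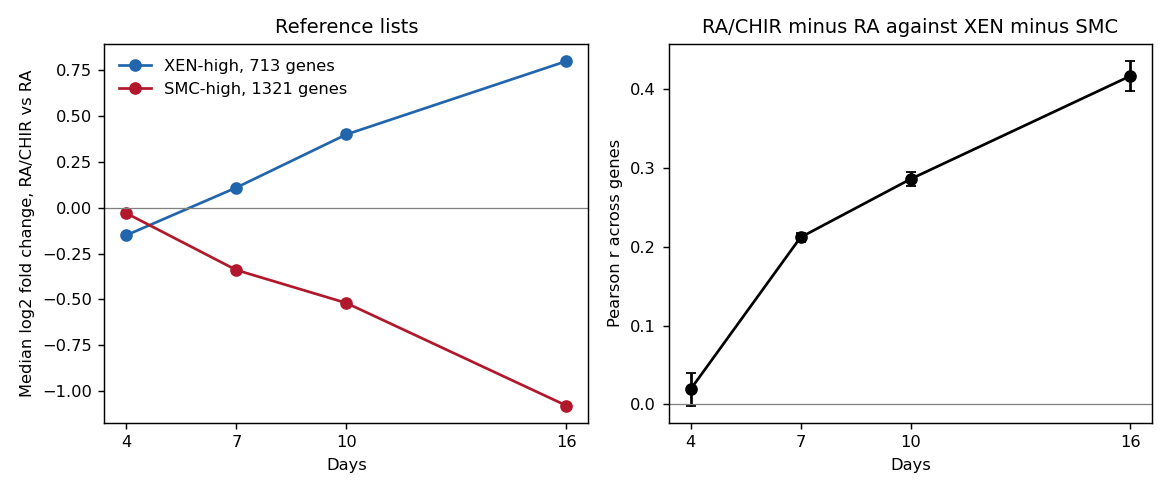
Left, median log2 fold change between RA/CHIR and RA of the 713 XEN-high and 1321 SMC-high genes by day of sampling; right, Pearson correlation across genes of that change with the XEN over SMC difference, with bars for the SD over single libraries. The correlation goes from 0.019 on day 4 to 0.417 on day 16.

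Against mES, the RA arm shows what changed in stem cells treated with retinoic acid and no CHIR. The mES grew with LIF on feeder fibroblasts and the treated cells on gelatin, and no untreated cultures were sampled on the later days. In both arms, effects of the inducers against mES are therefore not separable from those of the culture change and of time. Day 16 also follows 6 days without inducers. On day 4 the genes that rose most were Cyp26a1 (8.38 ± 0.12, adjusted p = 6.21e-27), Hoxa5 (107.8 ± 1.31 against 0.518 FPKM, 6.17), Cyp26b1 (5.92), the Hoxa antisense transcript Hotairm1 (6.15 ± 1.03, adjusted p = 8.64e-06) and Hoxb5os (60.5 FPKM, listed at 0 in all 3 mES libraries). Hoxb5os and Hotairm1 lie antisense to Hox genes, so their values are uncertain where strand was not kept. Nanog fell from 376.5 ± 12.2 to 0.611 (-7.87), Esrrb from 213.9 ± 14.1 to 0.916 ± 0.115 (-6.81), Utf1 by 6.50 and Klf2 by 6.60, and the muscle fusion gene Mymx from 308.1 ± 60.5 to 0.853 (-7.40). Hox genes rose in 28 of 36 (camera adjusted p = 6.03e-14). Retinoid response genes rose in 16 and fell in 1 of 20 (Rarb 5.66, Dhrs3 5.52, adjusted p = 4.33e-09), and primitive endoderm genes rose in 19 of 20 (Col4a2 4.20, Col4a1 4.19, Gata4 3.61, adjusted p = 1.34e-14). Pluripotency genes fell in 24 of 26 (adjusted p = 3.01e-15). On days 7 and 10 Ecm1 (7.25 and 8.30), the growth factor gene Igf2 (6.60 and 6.98) and Dlk1 (6.56 and 6.76) were among the 5 highest, with Igfbp5 (6.92) and Wt1 (6.73) on day 10. Lowest on day 10 were Utf1 (-8.88), Nanog (-8.11), Dppa5a (4924.9 ± 319.7 to 17.1 ± 2.14, -8.10), Tdgf1 (-7.79) and Mymx, listed at 0.

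On day 16 of RA, the enteric actin gene Actg2, the matrix genes Dcn and Col3a1 and the imprinted genes Igf2 and Dlk1 were the 5 highest over mES. Actg2 rose to 1720.1 ± 209.1 FPKM (9.64 ± 0.24, adjusted p = 1.50e-22), Dcn to 788.6 ± 26.8 (8.78), Igf2 to 3009.5 ± 157.9 (8.24), Col3a1 to 671.0 ± 113.6 (7.96) and Dlk1 to 1111.8 ± 72.3 (7.88). Acta2 (6.99), Tagln (6.65), Cnn1 (7.34), Myh11 (6.30 ± 0.11, adjusted p = 1.70e-25) and Col1a1 (6.11) rose as well. Contractile smooth muscle genes rose in 22 of 23 (median 4.73, Myl9 7.45, camera adjusted p = 5.80e-12) and fibroblast matrix genes in 24 of 24 (median 4.29, Lum 7.05, adjusted p = 6.50e-12). The mES grew on feeder fibroblasts, and any feeder RNA in the mES libraries was not separated from that of the stem cells. Primitive endoderm genes rose in 16 and fell in 1 of 20 (adjusted p = 7.13e-06, and adjusted p = 0.237 with an estimated correlation), with Gata4 (2.32), Gata6 (2.75), Sox17 (3.58) and Foxa2 (2.85) all higher than in mES. Interferon response genes rose in 15 of 15 (adjusted p = 3.48e-07), imprinted genes rose in 13 and fell in 1 of 16 (adjusted p = 1.05e-05), and Hox genes rose in 24 of 36 (adjusted p = 4.19e-07). Pluripotency genes fell in 25 of 26 (median -5.74, adjusted p = 3.61e-16) and proliferation genes in 23 of 24 (median -1.99, Mcm5 -3.10, adjusted p = 1.57e-12). Called genes numbered 3864, 4578, 5363 and 6057 on days 4, 7, 10 and 16, of which 1930, 2307, 2719 and 3369 were higher than in mES. Which direction holds the majority depends on the scaling: on day 16, quantile normalization gave 2886 higher and 3114 lower genes, which is 48.1% higher in place of 55.6%. The near even split of days 4, 7 and 10 also turned, to 1964 higher and 1855 lower, 2241 and 2242, and 2579 and 2662. With TMM-style scaling day 4 (2012 higher, 1835 lower) and day 10 (2640 and 2710) turned as well, and day 4 also with a pseudocount of 0.1 (2927 and 2463) or a filter at 5 FPKM (1728 and 1488).

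The same comparison for the RA/CHIR arm began on day 4 with Cyp26a1 (7.63 ± 0.12), the retinol transporter gene Stra6 (166.5 ± 8.65 against 1.41 FPKM, 6.14), Fgfbp3 (6.05) and Pitx1 (6.01), while Klf2 (-6.51), Utf1 (-5.98), Fos (-6.02 ± 0.41) and Tdgf1 (-9.07) fell. Wnt targets rose in 15 of 22 (median 2.19, Nkd1 5.20, Sp5 4.86, Cdx1 4.45, camera adjusted p = 2.76e-09), against 5 higher and 5 lower in RA-4d (adjusted p = 0.953). Retinoid response genes rose in 15 and fell in 3 of 20 (Tgm2 -5.21, adjusted p = 1.50e-07), and Hox genes rose in 27 of 36. S100g (8.09 and 9.07), Cyp26a1 (8.39 and 8.80), Pitx1 (7.28 and 7.56) and Tspan8 (6.00 and 6.91) were among the highest on days 7 and 10, with Cited1 (6.20) on day 7 and Aqp8 (6.52) on day 10. On day 16 the highest were Gkn2 (2161.1 ± 65.2 against 1.74 ± 0.773, 9.66 ± 0.27, adjusted p = 2.09e-21), Gkn1 (714.2 ± 14.2, 8.92 ± 0.12), both known from the stomach lining, Tff3 (194.6 ± 23.7, listed at 0 in all 3 mES libraries), Mgst2 (7.60) and Tspan8 (263.5 ± 11.3, 7.55). Nanog (-6.47), Utf1 (-6.10), Mymx (-6.04) and the mitochondrial Chchd10 (1009.9 ± 59.4 to 14.9 ± 2.42, -6.00) fell most among named genes, beside CT954323.3, listed at 0 on day 16. Pou5f1 fell by 3.17 on the log2 scale (adjusted p = 2.37e-10), to 10.8% of the mES mean. Visceral endoderm genes rose in 20 of 23 (median 3.47, Afp 7.38, Ttr 7.2, adjusted p = 3.65e-10). Parietal endoderm genes rose in 18 of 20 (Pth1r 5.79, adjusted p = 6.23e-12) and primitive endoderm genes in 18 of 20 (Aqp8 7.39, Col4a2 5.52, adjusted p = 5.43e-13, and adjusted p = 0.053 with an estimated correlation). Among epithelial genes 11 of 14 rose (Krt18 5.26, Krt19 5.12). Pluripotency genes fell in 23 and rose in 1 of 26 (median -3.33, adjusted p = 3.67e-10). Called genes numbered 3003, 4161, 4890 and 6000, of which 1495, 1986, 2335 and 2978 were higher than in mES. The majority of lower genes is not stable. It turned on day 4 (1509 higher, 1476 lower) and day 7 (2082 and 2036) under quantile normalization, and on days 4 (1522 and 1468), 7 (2086 and 2070) and 16 (3064 and 2942) under TMM-style scaling. With a pseudocount of 0.1 it turned on all 4 days, with 2450, 2977, 3282 and 3818 higher against 1989, 2814, 3196 and 3707 lower, and with a filter at 5 FPKM likewise.

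**Figure D4:**
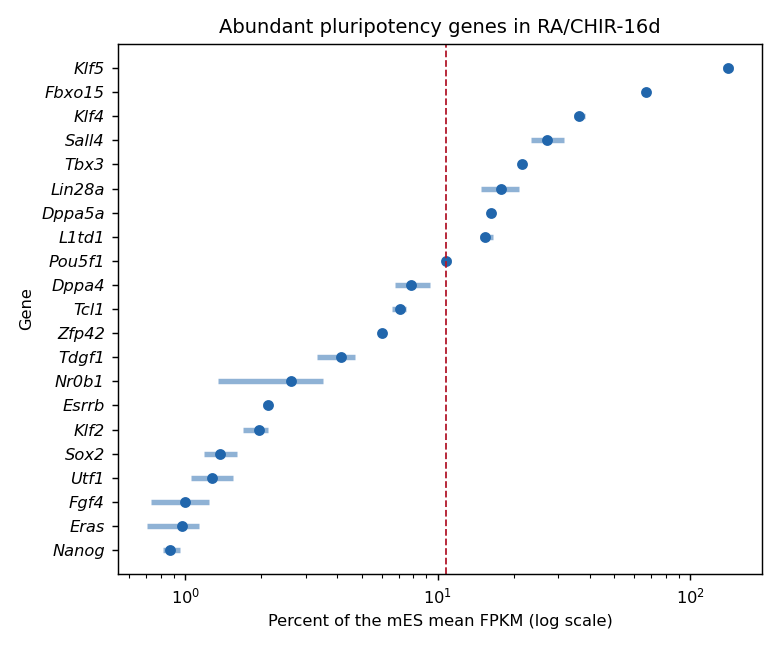
Level of abundant pluripotency genes in RA/CHIR-16d as a percent of the mES mean (log axis); points are means and bars run from the lowest to the highest of 3 libraries, with a dashed line at Pou5f1. Pou5f1 stands at 10.8%, Nanog at 0.867% and Klf5 at 141.9%. The spread of the mES libraries is not part of the bars.

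The reference lines themselves differed in 4905 genes, 2065 higher in XEN and 2840 higher in SMC. Under quantile normalization these were 2371 and 2315, so the larger number on the side of SMC depends on the scaling. Highest in XEN were Bex1 (9.02), the simple epithelial keratin genes Krt18 (694.4 ± 37.3 against 0.410 ± 0.149 FPKM, 8.95 ± 0.06, adjusted p = 6.12e-34) and Krt8 (8.55), Bex4 (8.93) and the X-linked homeobox gene Rhox5 (8.47). Highest in SMC were the matrix genes Col1a2 (5059.5 ± 66.8 against 0.176 ± 0.0261, -12.07 ± 0.16), Fbln2 (-11.76), Col1a1 (-10.94), the crosslinking enzyme gene Lox (-11.13) and the tropomyosin gene Tpm2 (-10.76). The endoderm regulators Gata4 (6.26), Sox17 (7.11 ± 0.15), Foxa2 (6.50) and Sox7 (3.52) were higher in XEN, and Acta2 (-6.27), Tagln (-5.55), Cnn1 (-7.21) and Myh11 (-4.00) in SMC. Gata6 (0.49) and Pdgfra (0.51) were not called. Fibroblast matrix genes were higher in SMC in 24 of 24 (median -7.10, camera adjusted p = 2.46e-17), as were contractile smooth muscle genes in 22 of 23 (adjusted p = 5.76e-11). Also higher in SMC were mesenchymal transition genes in 12 of 12 (adjusted p = 4.23e-08) and Hox genes in 25 of 36 (adjusted p = 1.19e-08). Primitive endoderm genes were higher in XEN in 13 of 20 (Aqp8 7.11, Foxq1 6.76, adjusted p = 3.01e-10, and adjusted p = 0.0939 with an estimated correlation). Visceral endoderm genes were higher in XEN in 11 and lower in 1 of 23 (Rbp4 6.40, adjusted p = 0.000139), and proliferation genes in 18 of 24 (adjusted p = 2.43e-11).

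RA/CHIR-16d was set against XEN to ask how near the treated cells come to the line. Gata4 (-0.41), Foxa2 (0.09), Sox17 (0.93) and Sox7 (-0.96) were not called, with Sox17 past the threshold under quantile normalization (1.15) and Sox7 under both scalings (-1.02 and -1.04). Gata6 differed, with libraries at 132.4 to 144.2 FPKM in RA/CHIR-16d and 41.2 to 44.7 in XEN. Higher in RA/CHIR-16d were the maternally expressed imprinted RNAs Meg3 (852.1 ± 8.05 against 0.355 ± 0.134 FPKM, 9.30 ± 0.07, adjusted p = 8.61e-33) and Rian (8.94), the secreted peroxidase Gpx3 (9.26), Gkn1 (8.88) and Dppa5a (796.1 ± 16.9 against 1.23, 8.50). Lower were Mid1 (-5.92), Ptk2b (-5.78) and the chemokine gene Ccl17 (4.07 ± 1.01 against 260.2 ± 33.7, -5.70). Rpl29 (-7.48) and Rps3a1 (-6.50) also headed the lower side, but these ribosomal protein genes have many processed pseudogenes, so their values are uncertain. Pou5f1 (6.88 ± 0.29, adjusted p = 4.29e-17), Zfp42 (4.74), Afp (6.52), Ttr (3.70), Col1a1 (6.21) and Cyp26a1 (7.09) were higher than in XEN. Visceral endoderm genes were higher in 17 and lower in 2 of 23 (Fgb 6.82, Apoa1 6.57, Trf 6.02, camera adjusted p = 1.69e-08). Primitive endoderm genes were higher in 12 of 20 (adjusted p = 0.000469, and adjusted p = 0.359 with an estimated correlation). Parietal endoderm genes were higher in 12 and lower in 2 of 20 (adjusted p = 0.00044, and adjusted p = 0.288 with an estimated correlation). Pluripotency genes were higher in 18 and lower in 1 of 26 (Tdgf1 4.97, adjusted p = 2.42e-08). Fibroblast matrix genes were higher in 19 of 24 (Col1a2 6.82, Col3a1 6.55, adjusted p = 3.67e-10), epithelial genes in 10 of 14 (Cldn6 6.46, adjusted p = 3.34e-05), and imprinted genes higher in 12 and lower in 1 of 16 (adjusted p = 1.12e-06). Proliferation genes were lower in 8 of 24 (adjusted p = 6.38e-10). Of 3822 called genes, 2396 were higher and 1426 lower than in XEN. The higher genes were thus 62.7% of calls, but 50.4% under quantile normalization, which shifts the median of all genes by -0.15. Across genes, the mean correlation between single libraries and those of XEN was 0.885, 0.877, 0.852 and 0.828 for the RA arm on days 4 to 16, and 0.878, 0.889, 0.886 and 0.876 for the RA/CHIR arm.

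RA-16d was compared with SMC in the same way. Tagln (-0.82) and Cnn1 (0.31) were not called, Acta2 was lower than in SMC (3683.0 ± 355.2 against 11435.1 ± 138.2 FPKM, -1.64 ± 0.16, adjusted p = 1.72e-09) and Myh11 higher (85.8 ± 24.7 against 15.6 ± 0.682, 2.35 ± 0.11). Contractile smooth muscle genes as a list were not called (3 higher, 6 lower of 23, adjusted p = 0.582), with Pgm5 (3.45) and Des (3.04) higher and Tpm2 (-1.77) lower. The imprinted genes Igf2 (3009.5 ± 157.9 against 0.503 ± 0.257, 10.98 ± 0.08), H19 (2455.6 ± 164.4 against 1.72, 9.83) and Dlk1 (8.63), the keratin gene Krt18 (7.95) and S100g (374.0 FPKM, listed at 0 in all 3 SMC libraries) were highest in RA-16d. Wisp2 (-9.60 ± 0.19), S100a4 (-7.49), the uncertain Rpl29 (-7.25) and the protease gene Ctsk (-6.42) were among the lowest. Endoderm regulators were higher in RA-16d: Gata4 (4.08), Sox17 (6.38), Foxa2 (4.83) and Gata6 (1.14). Epithelial genes were higher in 13 of 14 (median 4.95, camera adjusted p = 1.60e-10). Primitive endoderm genes were higher in 15 and lower in 1 of 20 (adjusted p = 1.15e-07, and adjusted p = 0.164 with an estimated correlation), and visceral endoderm genes higher in 15 of 23 (adjusted p = 6.69e-06). Fibroblast matrix genes were lower in 17 and higher in 4 of 24 (Mfap5 -6.35, Col1a2 -4.73, adjusted p = 0.000254, and adjusted p = 0.138 with an estimated correlation). In all, 4207 genes were called, 2476 higher and 1731 lower than in SMC. The excess of higher genes depends on the scaling, with 1931 higher and 1868 lower under quantile normalization. The mean correlation with SMC libraries across genes was 0.792, 0.82, 0.823 and 0.856 for RA and 0.783, 0.79, 0.789 and 0.781 for RA/CHIR on days 4 to 16, with 0.796 between XEN and SMC.

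Days 10 and 16 bracket the removal of the inducers together with a lower serum share, so those changes are not separable from time. In the RA arm, 1514 genes were called, 1217 of them higher on day 16, which is 80.4% of calls and 69.9% under quantile normalization. Postn (567.8 ± 29.2 against 4.31 ± 0.901 FPKM, 6.75 ± 0.20), the immediate early gene Nr4a1 (407.3 ± 117.8 against 3.20 ± 1.12, 6.59 ± 0.17), the pepsinogen gene Pgc (6.46), Lum (6.24) and the interferon target Isg15 (96.4 ± 3.99 against 0.495, 6.04) rose most. Cyp26b1 (60.4 ± 3.27 to 0.980, -4.96), Ecm1 (-3.86) and Hoxd1 (-3.63) were among those that fell most, with Exosc6 (-3.98), a gene inside a neighbour's transcript whose value is uncertain. Cyp26a1 was not called (-0.95), though it passes under quantile normalization (-1.23). Pou5f1 fell by 1.13 (adjusted p = 0.00265), but without RA-16d replicate 3 the change is -0.97 and not called. Contractile smooth muscle genes rose in 22 of 23 (Cnn1 4.64, Myh11 4.43, Des 3.66, camera adjusted p = 8.63e-22) and fibroblast matrix genes in 22 of 24 (Eln 6.01, Lox 5.43, adjusted p = 9.65e-23). Interferon response genes rose in 12 of 15 (Oasl2 3.96, adjusted p = 5.89e-15), immediate early genes in 11 of 11 (Fosb 5.84, Egr1 4.60, adjusted p = 8.97e-13) and glycolysis and hypoxia genes in 13 of 17 (Egln3 2.75, Bnip3 2.42, adjusted p = 4.33e-09, and adjusted p = 0.116 with an estimated correlation). Hox genes fell in 13 of 36 (adjusted p = 4.84e-09).

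In the RA/CHIR arm, 2435 genes were called between days 10 and 16, 1399 higher and 1036 lower on day 16. Gkn2 (10.92 ± 0.27), Gkn1 (9.43), Tff3 (7.35), Afp (6.61 ± 0.28) and Apoa1 (6.54) rose most. The Wnt targets Notum (102.9 ± 3.04 to 0.201 FPKM, -6.45 ± 0.15), Sp5 (-4.71) and Nkd1 (104.9 ± 3.05 to 3.93 ± 0.666, -4.43) fell most, with Ppp1r17 (-4.81) and the antisense transcript Tbx3os1 (-4.26 ± 0.59). Dab2 (3.43), Gata6 (2.13), Foxa2 (1.44), Nanog (1.79) and Col1a1 (4.28) rose, Axin2 (-4.26), Lef1 (-2.22) and Cyp26a1 (-2.85) fell, and Pou5f1 (-0.44) and Sox17 (0.11) were not called. Visceral endoderm genes rose in 18 and fell in 1 of 23 (Ttr 5.76, Fgb 5.64, camera adjusted p = 6.38e-10). Immediate early genes rose in 11 of 11 (Fosb 4.84, Fos 3.42, adjusted p = 2.28e-07, and adjusted p = 0.101 with an estimated correlation), as did interferon genes in 9 of 15 (Isg15 3.48, Irf7 2.71, adjusted p = 6.10e-05). Rises were also found in cholesterol synthesis genes in 9 of 17 (Insig1 3.88, adjusted p = 3.30e-06, and adjusted p = 0.222 with an estimated correlation). Fibroblast matrix genes rose in 17 and fell in 1 of 24 (Col1a2 5.22, adjusted p = 1.79e-08). Wnt targets fell in 15 and rose in 1 of 22 (adjusted p = 9.07e-09). Retinoid response genes fell in 13 and rose in 1 of 20 (Tgm2 2.72, Cyp26b1 -2.11, adjusted p = 1.07e-05) and Hox genes fell in 14 of 36 (adjusted p = 1.46e-09).

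The interaction asks for which genes the step from day 10 to day 16 differed between the arms, and 2448 genes were called, 993 with a more positive step in the RA/CHIR arm and 1455 with a more negative step. Apoa1 was highest (7.84 ± 0.23, adjusted p = 2.33e-19), with a step of -1.31 in RA and 6.54 in RA/CHIR, followed by Fgb (5.94), Gkn2 (5.82, with steps of 5.11 and 10.92), Ttr (5.67) and Zg16 (5.65). The connective tissue gene Ogn was lowest (-6.43 ± 0.12, with steps of 3.42 and -3.01), then Eln (-6.09), Pitx1 (-5.72, with steps of 2.98 and -2.75), Pgc (-5.72) and Lum (-5.61). Identity genes with a call were Afp (5.02), Dab2 (3.09), Gata6 (2.07), Nanog (1.53), Zfp42 (1.27), Myh11 (-4.20), Cnn1 (-2.90), Axin2 (-2.90), Cyp26a1 (-1.90), Pdgfra (-1.73), Lef1 (-1.43) and Sox17 (-1.36). Pou5f1 (0.69), Acta2 (-0.56), Tagln (-0.33), Col1a1 (0.10) and Gata4 (-0.07) were not called. Visceral endoderm genes were higher in 17 and lower in 1 of 23 (median 2.41, camera adjusted p = 2.20e-10). Wnt targets were lower in 14 and higher in 2 of 22 (Notum -4.77, Nkd1 -4.68, Apcdd1 -3.97, adjusted p = 4.19e-07), and interferon genes lower in 8 of 15 (Bst2 -3.10, adjusted p = 4.88e-07). For contractile smooth muscle, genes were lower in 12 of 23 (Des -3.81, adjusted p = 2.94e-08), and fibroblast matrix genes lower in 12 and higher in 3 of 24 (adjusted p = 7.35e-06, and adjusted p = 0.0705 with an estimated correlation).

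Over all 18 comparisons, 286 of 648 pairs of list and comparison were called at the preset correlation, and 164 of these hold with an estimated correlation. Every list call given here without a value for an estimated correlation holds with it. In RA/CHIR against RA, 13, 14, 15 and 18 lists were called on days 4, 7, 10 and 16, of which 7, 8, 8 and 11 hold. Calls not described above include two-cell-like genes on day 7 (3 of 15 higher, median 0.70, adjusted p = 2.84e-05), whose Zscan4 members are close paralogs. Proliferation genes on day 16 had 0 higher and 1 lower member of 24 but a raised median (0.36, adjusted p = 0.000957, and adjusted p = 0.0539 with an estimated correlation). Between the arms, the lists for formative epiblast, primitive streak, neural crest, skeletal muscle, endothelium, blood, trophoblast, cartilage and bone, BMP and TGF-beta response, germ cells, X and Y linked genes and clustered histone genes were called on no day. Single members still changed: on day 16, 8 of 17 BMP and TGF-beta genes were lower and 3 higher (camera adjusted p = 0.0682). Some of these lists were small, with 4 blood and 5 skeletal muscle genes measured. Median, mean and test differed in sign for 57 pairs, none of them called. Adjusted over the list alone, the counts of higher and lower members were the same in all but 12 pairs, all of histone genes or visceral endoderm genes. For visceral endoderm genes these are RA/CHIR-7d against RA-7d (3 lower over all genes and 4 over the list alone) and RA-16d against RA-10d (4 and 5 higher). Some lists share members, such as 5 genes of both primitive and parietal endoderm and 3 of both primitive and visceral endoderm, so their results are not independent.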

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

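The tests of explanations and the regroupings reported here were chosen after the result was seen, while the interaction test was planned. Results whose step from day 10 to day 16 differed between the arms by the interaction test come first. Of the genes tested, 2448 met this. The 3 patterns weighed further below were not picked by that test. Ogn (-6.43), Eln (-6.09), Lum (-5.61), Pitx1 (-5.72) and Pgc (-5.72) had a more negative step with RA/CHIR. Apoa1 (7.84), Fgb (5.94), Gkn2 (5.82), Ttr (5.67) and Zg16 (5.65) had a more positive step. Among the identity genes, Afp (5.02), Dab2 (3.09), Gata6 (2.07), Nanog (1.53) and Zfp42 (1.27) stepped further up with RA/CHIR. Myh11 (-4.20), Cnn1 (-2.90), Axin2 (-2.90), Cyp26a1 (-1.90), Pdgfra (-1.73), Lef1 (-1.43) and Sox17 (-1.36) stepped further down or rose less. Axin2 and Cyp26a1 are targets of the inducers that were removed after day 10, and their steps in RA/CHIR were -4.26 and -2.85 against -1.36 and -0.95 in RA.

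The count of 2448 was set against 100 regroupings of the 12 libraries of these 4 groups. In 16 of the 100, the real one included, as many genes were called, with 4049 as the highest other value. Such regroupings carry the effects of day and of treatment into the interaction, so they do not test it alone. The effects of day and treatment were then kept in place and only what remained was regrouped. In this form 1 of 100, the real one, gave as many genes, and the highest other value was 1148. This form treats the 12 libraries as independent, but the labels do not say whether the replicates are separate cultures. What was regrouped still held the real interaction, so the other counts do not measure the spread between libraries alone. The real count was above all regroupings of this form, while chance differences between cultures are not excluded.

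For the comparisons of 2 groups, 10 regroupings of 6 libraries exist, which is too few for a share under 0.05. Every other regrouping mixes libraries of both groups, so the real difference enters the spread and low counts follow by construction. The highest others given here are therefore no measure of chance. In RA/CHIR against RA, the real counts were 1259, 1762, 2546 and 3514 on days 4, 7, 10 and 16, and the highest others 2, 1, 1 and 4. For RA against mES they were 3864, 4578, 5363 and 6057 with highest others of 3, 2, 5 and 10, and for RA/CHIR against mES 3003, 4161, 4890 and 6000 with 5, 1, 2 and 5. XEN against SMC gave 4905 (highest other 3), RA/CHIR-16d against XEN 3822 (2), RA-16d against SMC 4207 (2), RA-16d against RA-10d 1514 (3), and RA/CHIR-16d against RA/CHIR-10d 2435 (1).

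Pou5f1 in RA/CHIR-16d is the first pattern weighed, and the interaction test did not call it (0.69, adjusted p = 0.187). It remained at 143.7 ± 5.15 FPKM, 10.8% of the mES mean with libraries between 10.5 and 11.3%, while RA-16d had 4.31 ± 1.08. This range leaves out the spread of mES itself, whose libraries stood at 1141.6, 1126.2 and 1709.5 FPKM. If leftover undifferentiated cells with the mES profile carried it, other abundant mES transcripts would stand near the same share. Of 20 other pluripotency genes with at least 50 FPKM in mES, 9 had their highest library below 50% of the share of Pou5f1: Nanog (0.867%), Eras (0.970%), Fgf4 (0.998%), Utf1 (1.27%), Sox2 (1.37%), Klf2 (1.95%), Esrrb (2.13%), Nr0b1 (2.63%) and Tdgf1 (4.14%). This argues against leftover mES-like cells as the source of all of the Pou5f1 signal. Scaling is argued against as well, since the change from RA-16d, 4.79 without scaling, was at least 4.87 under both other scalings. Open is expression kept by part or all of the treated cells: 8 of the 20 genes stood at or above the share of Pou5f1, namely L1td1 (15.4%), Dppa5a (16.2%), Lin28a (17.8%), Tbx3 (21.6%), Sall4 (27.0%), Klf4 (36.3%), Fbxo15 (66.9%) and Klf5 (141.9%), and 3 lay between, Zfp42 (6.04%), Tcl1 (7.12%) and Dppa4 (7.84%). Bulk RNA keeps this open, and cells of part and of all of the culture cannot be told apart.

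The differences of the treated cells from the reference lines are the second pattern. Without genes on chromosomes X and Y, 3682 genes were called between RA/CHIR-16d and XEN in place of 3822, and 4037 between RA-16d and SMC in place of 4207. Only 576 of the tested genes lie on X or Y, so leaving them out cannot lower either count by much, and this test decides nothing about the X and Y dosage of the line. The called genes lay on X or Y in 3.66 and 4.04% of cases, against 3.49% of tested genes. Effects of X and Y dosage on genes of other chromosomes were not tested. The lines and the stem cells differ in sex-linked RNA: the Y-linked Eif2s3y was at 49.2 ± 3.01 FPKM in mES, 0.223 in SMC and listed at 0 in XEN, and Xist was at 0.567 in mES, 41.2 ± 1.64 in SMC and 97.8 ± 7.77 in XEN. The labels do not give the animal or strain of each line or its time in culture, and how much these add to the called differences is confounded with the groups. An origin of the line from another animal may thus add to these differences, and neither it nor X and Y dosage can be told apart from cell type: each line is a single group.

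The third pattern is the immediate early genes, which rose in 11 of 11 cases in both arms between days 10 and 16. Under quantile normalization 11 of 11 still rose in both arms, which argues against scaling. For 11 of 11, all 6 libraries of day 16 lay above all 6 of day 10 and also above all 18 libraries of days 4, 7 and 10. Against mES, by contrast, 9 of 11 were lower on each of days 4, 7 and 10 with RA and 8 of 11 with RA/CHIR, though none of these list calls holds with an estimated correlation. On day 16, RA had 7 higher and 0 lower than mES (adjusted p = 0.0152, and adjusted p = 0.44 with an estimated correlation), and RA/CHIR 3 higher and 2 lower, not called as a list (adjusted p = 0.441). For most of these genes the rise from day 10 thus starts from a level below mES. These genes respond within minutes to handling and to serum, and the list calls in RA (adjusted p = 8.97e-13) and RA/CHIR (adjusted p = 2.28e-07, and 0.101 with an estimated correlation) mark the same day. Handling at harvest may explain this, and so may the withdrawal of the inducers with the lower serum. All libraries of day 16 share the withdrawal and the lower serum, and they may share a handling at harvest, so the explanations cannot be told apart. The rise was not of the same size in both arms: by the interaction test 0 of 11 rose more and 6 rose less with RA/CHIR (median -1.14, adjusted p = 0.00775, and adjusted p = 0.403 with an estimated correlation), and 7 of 11 were lower in RA/CHIR-16d than in RA-16d. The cause of this difference was not tested.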

How the results depend on the processing

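The runs without X and Y genes, and the runs of the gene lists under other scalings and with the replicate block, were tests chosen after the result was seen. The other alternatives were planned. Fewer genes passed or more passed, but no count of changed genes moved by over 1.5 times under TMM-style scaling, quantile normalization, no filter, a filter at 5 FPKM, a fit of only the groups compared, no variance trend, or the replicate block.

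With a pseudocount of 0.1, which compresses low values less, counts rose to 2192, 2964 and 3888 for RA/CHIR against RA on days 4, 7 and 10, to 2339 for RA-16d against RA-10d and to 3820 for RA/CHIR-16d against RA/CHIR-10d. Without a minimum fold change, which by construction admits small changes, the counts were 7084 (3544 higher and 3540 lower, without the excess of lower genes), 7812, 9112 and 10216 for RA/CHIR against RA, 10844, 11420, 11886 and 12280 for RA against mES, 9966, 11094, 11430 and 12128 for RA/CHIR against mES, 10744 for XEN against SMC, 10503 for RA/CHIR-16d against XEN, 10948 for RA-16d against SMC, 6869 and 9086 for day 16 against day 10 in RA and RA/CHIR, and 7154 for the interaction.

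Leaving out each library in turn gave 1266 to 1282, 1777 to 1804, 2567 to 2600 and 3536 to 3593 genes for RA/CHIR against RA, 3846 to 3933, 4501 to 4673, 5288 to 5452 and 5986 to 6117 for RA against mES, and 2995 to 3051, 4157 to 4213, 4865 to 4964 and 5946 to 6067 for RA/CHIR against mES. The ranges were 4897 to 4935 for XEN against SMC, 3780 to 3875 and 4163 to 4302 for the treated cells against XEN and SMC, 1504 to 1541 and 2454 to 2475 for day 16 against day 10, and 2396 to 2539 for the interaction.

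The XEN-high genes on day 7 lost their call under TMM-style scaling (median 0.12, adjusted p = 0.0595), quantile normalization (0.13, 0.0701) and a pseudocount of 0.1 (0.15, 0.0674). On day 4 they lost it with a pseudocount of 0.1 (-0.09, 0.0853), and the SMC-high genes gained a call without a filter (-0.03, 0.0262). The correlations with the XEN over SMC difference on days 7, 10 and 16 were 0.193, 0.267 and 0.393 with a pseudocount of 0.1, and 0.227, 0.302 and 0.437 with a filter at 5 FPKM, moving by more than their spread. The cause was not tested.

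Of 648 pairs of list and comparison, 164 were called with an estimated correlation, against 286 at the preset one, because correlated members by construction widen the test. TMM-style scaling ended 2 list calls and added 8, quantile normalization ended 16 and added 11, and the replicate block ended 0 and added 2. In the latter, 288 pairs were called. Of 2300 calls of named genes, 2176 held under every alternative that was run for them and 124 were lost under at least 1. Apart from the identity genes, these genes were picked among called genes by the size of their change in the main fit. Their share thus does not extend to calls near the threshold, and leaving out the minimum fold change cannot end a call. Of 2434 named pairs of gene and comparison, called or not, 2285 passed the filter at 5 FPKM and 268 were part of the runs without X and Y genes. In RA-10d against mES, mt-Atp8 went from 1.03 to 0.00 under quantile normalization. It is the highest gene in all 3 RA-10d libraries and in mES replicates 1 and 2, and the method by construction gives the top rank the same value in every library, so this says nothing about the change. Quantile normalization shifted the median of all genes by -0.15 in RA/CHIR-16d against XEN.

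The labels do not say that replicate numbers pair the groups, and whether they do stays open. Residuals of libraries with the same number were correlated at 0.055, 0.07 and 0.041 in RA/CHIR-4d against RA-4d, at 0.103, 0.039 and 0.096 in RA/CHIR-7d against RA-7d, and at 0.068, 0.104 and 0.031 in RA/CHIR-10d against mES. In these comparisons all 3 libraries correlated best with their own number, but in no comparison were all 3 values above 0.1, and in RA/CHIR-10d against RA-10d they were -0.076, 0.024 and -0.004. With the number as a block, RA/CHIR against RA gave 1260, 1764, 2544 and 3514 genes. The absolute depth behind each FPKM is unknown, so weakly expressed genes listed at 0 cannot be called absent. Relative depth was estimated from the most frequent ratio of values under 0.3 FPKM in mES replicate 1 to those in each library. This relative depth ran from 0.657 to 1.165. It was 0.714, 0.657 and 0.75 in RA/CHIR-16d against 0.714, 0.963 and 0.901 in RA-16d.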

Other observations

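The genes below were chosen after their values were seen, and no tests were run on them beyond those of all genes and lists. Some imprinted and sex-linked RNAs differed in level between a line and the treated cells. Meg3 and Rian of the Dlk1 locus stood at 0.355 and 0.185 FPKM in XEN, against 751.8 ± 40.6 and 512.6 ± 30.6 in SMC and 852.1 ± 8.05 and 575.7 ± 11.9 in RA/CHIR-16d. Igf2 was at 0.361 in XEN and 0.503 in SMC, and at 3009.5 ± 157.9 in RA-16d. Peg3 stood at 96.1 ± 8.27 in XEN and 0.328 in SMC. Xist, the RNA of the inactive X chromosome, was at 97.8 ± 7.77 in XEN and 41.2 ± 1.64 in SMC, and at 0.567 in mES. The Y-linked Eif2s3y was at 49.2 ± 3.01 in mES, 53.6 ± 2.37 in RA-16d and 55.0 ± 4.06 in RA/CHIR-16d, at 0.223 in SMC, and listed at 0 in XEN.

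A few genes known from the lining of the stomach or the intestine were looked up, without a list or a test of that group. Gkn2 stood at 100.3 ± 6.36 FPKM in RA-16d, 2161.1 ± 65.2 in RA/CHIR-16d and 6.06 in XEN. Gkn1 was at 40.7 ± 3.41 and 714.2 ± 14.2 in RA-16d and RA/CHIR-16d, and Tff3 at 12.9 and 194.6 ± 23.7. Pga5 was at 61.8 ± 3.18 in RA-4d and 48.7 ± 3.95 in RA-16d, at 2.17 ± 0.615 in RA/CHIR-4d and 495.0 ± 8.33 in RA/CHIR-16d, and at 58.5 in XEN, while its relative Pgc was higher with RA alone, at 137.9 ± 7.74 against 7.47 ± 1.36 on day 16. Zscan4c, a marker of the rare state of stem cells that resembles the early embryo, stood at 15.0 ± 1.56 in mES, 13.1 ± 0.897 in RA-4d, 21.6 ± 0.783 in RA/CHIR-4d and 2.38 in RA/CHIR-7d, and was listed at 0 in RA-10d and RA-16d. Its paralogs are close, so its value is uncertain.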
